A study of Homo sapiens with 7 samples.

How the data were processed

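Palmar fascia from 4 donors with Dupuytren's disease and 3 control donors was analysed, 1 library per donor, with the group taken from the disease status in the labels. Replicate numbers were given in the order of the deposited samples and pair no samples. Per the labels' protocols, tissue was kept in RNAlater and RNA was extracted on RNeasy columns. Per the same protocols, libraries were made from a low input of total RNA with a SMARTer stranded total RNA kit. Such a kit keeps noncoding transcripts and amplifies the product. Per the submitters' processing notes, STAR and RSEM were used with the build GRCh38.p12. The roles of these tools, their versions, the annotation release, the strand setting and any filter on genes are not given in the sources used here. The deposited values are expected counts per gene as whole numbers, which the authors had not scaled to depth, as the differing library totals show. Low input and amplification mean that reads are not independent molecules, so intervals cover counting error only, and DNA left in the RNA would be counted as expression in such a total RNA library.

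Each file held the same 31963 gene identifiers. Names, gene types, exonic lengths and coordinates came from GENCODE 29, an annotation of GRCh38, matched on the identifier without its version: 31916 matched, 30835 of them with the same version, and 47 had no name. Genes of the Y chromosome, XIST and TSIX (49 in all) were left out before any test because the samples are human donors. The 1 unit used, expected counts as deposited by the authors, was rounded to whole numbers, which changed no value already whole.

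Genes were kept by edgeR's filterByExpr with the group (22012 genes) and scaled by TMM factors, which were 0.646 to 0.934 in Dupuytren's and 1.22 to 1.59 in control libraries. Groups were compared by edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust, two-sided, no covariate), with Benjamini-Hochberg adjusted p under 0.05 as a call. CPM values are means ± SD of TMM-scaled CPM unless named library CPM, which divide by the library total, and log2 CPM used a prior count of 2. The SE of a log2 fold change was derived from the fold change and its F statistic. With 3 and 4 libraries the common biological coefficient of variation was 0.46.

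In all, 36 gene lists (607 different genes) were written from textbook knowledge before the data were examined: 16 of themes such as collagens, contraction, cytokines and energy metabolism, 3 related to RNA quality or composition and 17 of cell types. Lists with at least 5 measured members (34) were tested by limma's camera on log2 CPM with a preset correlation of 0.01, and again with an estimated correlation, by ranks and by fry. Named genes followed a rule set before the data were examined. It took the 10 genes with the smallest p in each direction among those with an official symbol, libraries that did not overlap between groups and a mean log2 CPM of at least 2, leaving out pseudogenes and clone names. It then took up to 3 genes with the smallest p from each list that was called or had a called member, and the fixed genes COL1A1, COL3A1, POSTN, TNC, FN1, ACTA2, MMP14, TGFB1, SFRP4, IL6, TNF, IL1B and CCL2. Genes outside the rule, such as CD74, GAPDH, LDHA, NORAD, CSPG4, DES, ADIPOQ, PIP, KRT1 and KRT9, were chosen after their values were seen. Library measures were compared by exact permutation over the 35 splits, and gene types by Fisher's exact test.

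The test was run on simulated counts with the real means, dispersion and depths (22012 genes simulated, 19691 tested). Of 100 genes changed 2-fold 7% were recovered, and of 100 changed 4-fold 59%, with 77 calls in all, 9 of them false and 2 in a gene list that was shifted as a whole. That list was recovered, with 0 of the other lists called. The simulation did not carry over the correlation between genes, so it cannot show how often camera calls lists falsely in the real libraries. The estimated correlation there was 0.87 for the cytosolic ribosomal protein list, and each of the 34 other splits of the libraries gave at least 5 list calls. No 2 libraries of a group agreed within sampling noise (smallest chi-square per degree of freedom 7.77), so all 7 were counted.

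Alternatives set before the data were examined were median-ratio and upper-quartile factors, library sizes alone, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, leaving out mitochondrial and ribosomal RNA genes, protein-coding genes only, 1 surrogate variable (sva 3.50.0), the 500 most variable genes for the principal components, and leaving out each library. Alternatives added after seeing the data were subtraction of a background (per library, olfactory receptor reads per kb of exon times each gene's exonic length), abundant protein-coding genes only (mean log2 CPM of at least 5) with their own TMM factors, and thinning of every library to the smallest total. Sex-linked genes and variants were not analysed here. A few genes that the rule names, and a cell type list that rested on one of them, are not reported here, although all genes stayed in the tests and counts, except that these genes were left out of the search for single libraries that stood apart.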

Results

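Gene expression was measured by total RNA sequencing in palmar fascia, the fibrous sheet under the skin of the palm. Tissue from donors with Dupuytren's disease, a fibrosis of this sheet that draws the fingers into the palm, gave 4 libraries, and control tissue gave 3. The groups differed in depth before any gene was compared. Total counts were 11606701, 9982421, 6433195 and 14027954 in Dupuytren's 1 to 4, against 1828632, 1550389 and 2779530 in Control 1 to 3 (two-sided exact permutation test, p = 0.0571; the smallest p that 35 splits allow is 0.0286).

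Reads on genes foreign to connective tissue were more frequent in the control libraries. Reads on 248 olfactory receptor genes, which encode odorant receptors of the nose, made up 1022, 2155 and 684 CPM (counts scaled to a common library total) in Control 1 to 3, and 49.4, 50.6, 219 and 23.5 CPM in Dupuytren's 1 to 4 (exact permutation p = 0.0286, and 0.0643 after Benjamini-Hochberg adjustment over 18 library measures). The 95% Wilson intervals of the nearest libraries, 207 to 230.3 CPM in Dupuytren's 3 and 654 to 716 CPM in Control 3, did not overlap, and cover counting error only. Control libraries also held reads on more genes (29689 to 30490 against 24035 to 27134) despite their lower depth, and a larger share of counts on processed pseudogenes (1.61% ± 0.773, SD, n = 3, against 0.402% ± 0.0738, n = 4; exact p = 0.0286, adjusted 0.0643). These measures separated the libraries by group, so no comparison within one level of depth or of olfactory receptor reads could be made. Every difference between the groups given here stands beside them.

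**Figure D1:**
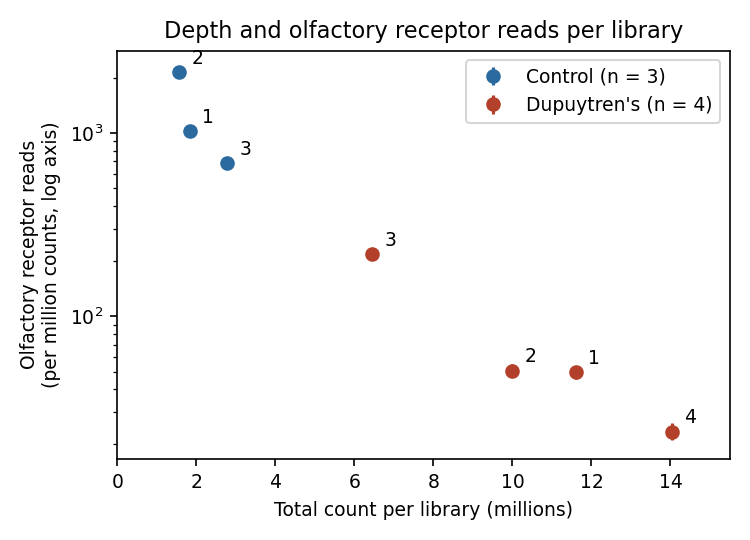
Reads on olfactory receptor genes in CPM (log axis) against the total count of each library, with 95% Wilson intervals mostly smaller than the points and the replicate number beside each point. The 3 control libraries lie at 684 CPM or more and the 4 Dupuytren's libraries at 219 CPM or less.

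The main comparison asked which genes differ between fibrotic and control fascia. Among the genes with the smallest p for higher levels in Dupuytren's tissue were MGP, which encodes the matrix Gla protein, an inhibitor of calcification, and HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor. MGP stood at 1168 ± 568 CPM (SD, n = 4) against 194 ± 63.2 (n = 3), and HIF1A at 118 ± 11.7 against 29.8 ± 15.4. CSRP2, a LIM-domain protein of smooth muscle, stood at 47.1 ± 17.2 against 10.2 ± 2.80. PTGFR, the prostaglandin F receptor, and GUCY1A1, a subunit of the nitric oxide receptor guanylate cyclase, were higher by 1.79 ± 0.30 and 1.86 ± 0.32 on the log2 scale (± SE). The genes named as lower were of low abundance. The long noncoding RNA SAMMSON stood at 1.96 ± 1.30 against 29.1 ± 10.5.

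Groups did not overlap in 37.3% of tested genes, where chance gives 5.71%. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.0158 for MGP, PTGFR and GUCY1A1. It was 0.0143 for HIF1A and CSRP2 and 0.00846 for SAMMSON. The other genes named by the rule as higher were EIF3CL, C4orf3, NEK7, EI24 and ZC3H11A, with log2 fold changes of 1.45 to 1.61. EIF3CL shares reads with its near-identical copy EIF3C, so its value is uncertain. Of the 10 genes named as higher, CSRP2 alone was still called after subtraction of the olfactory receptor background. MGP, HIF1A, PTGFR and GUCY1A1 did not pass there (edgeR adjusted p = 0.0531, 0.0531, 0.0533 and 0.0741). EIF3CL, C4orf3, NEK7, EI24 and ZC3H11A did not pass either (edgeR adjusted p from 0.0537 to 0.120). The others named as lower were INTS6-AS1, PRICKLE2-AS1, TMEM132B, FBXO40, PCDHB1, HMGA2, PCAT1 and PCA3, with log2 fold changes of -3.61 to -2.24. Of these, TMEM132B and FBXO40 were still called after subtraction of the olfactory receptor background. INTS6-AS1, PRICKLE2-AS1, PCDHB1 and PCAT1 were not. HMGA2 and PCA3 had too few reads left to test, so their control reads cannot be told apart from that background. The antisense genes INTS6-AS1, PRICKLE2-AS1, PCAT1 and PCA3 may share reads with genes on the opposite strand, because the strand setting of the counting is not given in the sources used here. MGP lies on GRCh38 chromosome 12 from 14881181 to 14885926 and CSRP2 on the same chromosome from 76858715 to 76879060. HIF1A lies on chromosome 14 from 61695513 to 61748259. SAMMSON lies on chromosome 3 from 69999550 to 70518064. Each value is the authors' estimate for the whole gene.

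Over all genes, 3439 of 22012 tested were called at an adjusted p under 0.05, of which 1440 were higher and 1999 lower in Dupuytren's tissue. Without Control 2 the same edgeR test called 0 genes, with 4220 at an unadjusted p under 0.05. Without Control 1 it called 46 and without Dupuytren's 1 it called 528. Without Dupuytren's 2 it called 1018, without Dupuytren's 4 it called 1955 and without Dupuytren's 3 it called 6007. The balance of directions followed the scaling: 41.9% of calls were higher with TMM factors, 28.7% with median-ratio factors, 11.6% with upper-quartile factors and 2.06% with library sizes alone. The median log2 fold change over all genes was -0.016 with TMM factors and -0.75 with library sizes alone. A set of 4986 abundant protein-coding genes (mean log2 CPM of at least 5) had a median of 0.54 with TMM factors and -0.18 with library sizes alone.

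The 2 directions held different kinds of gene. Protein-coding genes made up 91.1% of the higher calls (1312) and 41.8% of the lower calls (836). Small nucleolar RNAs, which guide the modification of ribosomal RNA, were called higher in 58 of 121 tested and lower in 0 (Fisher's exact test against all other genes, adjusted p = 1.4e-35 for higher over 40 tests). Processed pseudogenes were called lower in 378 of 1559, long intergenic noncoding RNAs in 317 of 1439 and antisense genes in 191 of 1136 (adjusted p = 3.7e-76, 8.3e-53 and 9.0e-17). The lower calls had a median level of 7.38 CPM in control and 0.601 CPM in Dupuytren's libraries. Genes are not independent replicates, so these tests describe the calls in these libraries.

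Fibrillar collagens were high in Dupuytren's 1 and 3 and close to the control level in Dupuytren's 2 and 4. The collagen list had a mean log2 CPM of 9.56, 8.10, 9.74 and 7.83 in Dupuytren's 1 to 4. The adipocyte list, at 3.97, 7.57, 2.87 and 6.16, and the sweat gland list, at 3.39, 5.83, 2.19 and 5.32, ran the other way. COL1A1, the main chain of type I collagen, stood at log2 CPM 13.07, 10.56, 13.48 and 9.30 in Dupuytren's 1 to 4 and between 9.58 and 10.17 in the controls. Its difference of 2.50 ± 0.88 (log2, SE) did not pass the test (edgeR adjusted p = 0.0706). COL3A1, of type III collagen, gave 2.25 ± 0.75 (adjusted p = 0.0589). COL14A1 and COL5A2 were the collagens that rose, by 2.07 ± 0.57 and 1.62 ± 0.49. Of the 18 collagens of the list, 2 were called higher over all genes and 0 when adjusted over the list alone, and the list was called higher by camera with its preset correlation (adjusted p = 0.0046; adjusted p = 0.667 with an estimated correlation).

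Several matrix glycoproteins were higher in Dupuytren's tissue. SPARC, a collagen-binding matricellular protein, rose by 2.65 ± 0.63 on the log2 scale, CTHRC1, a secreted protein of activated fibroblasts, by 1.91 ± 0.43 and the small proteoglycan OGN by 2.05 ± 0.44. POSTN, or periostin, had a difference of 3.41 ± 0.97, with log2 CPM from 4.96 to 8.75 in Dupuytren's and 3.46 to 4.60 in control libraries, and did not pass (edgeR adjusted p = 0.0526). FN1 (1.26 ± 0.59, adjusted p = 0.135) and TNC (1.05 ± 0.68, adjusted p = 0.282) did not pass. In this list 5 of 22 members were called higher, 7 when adjusted over the list alone (camera adjusted p = 0.0045; adjusted p = 0.663 with an estimated correlation).

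Genes of collagen maturation and of contraction were also higher. PLOD2 and P4HA1, which hydroxylate collagen, and LOX, which crosslinks it, rose by 1.27 ± 0.28, 1.30 ± 0.29 and 1.37 ± 0.37 (LOX by 0.90 without Dupuytren's 3). Of that list 4 of 19 members were called higher, 4 when adjusted over the list alone (camera adjusted p = 0.0080; adjusted p = 0.670 with an estimated correlation). ACTA2, the smooth muscle actin of myofibroblasts and of vessel walls, stood at 243 ± 30.3 CPM against 88.9 ± 50.1. This was a rise of 1.44 ± 0.37 (edgeR adjusted p = 0.0294), with PALLD (1.49 ± 0.27) and TPM2 (0.91 ± 0.24), both of actin filaments. After subtraction of the olfactory receptor background ACTA2, PALLD and TPM2 were at 0.73, 0.87 and 0.18 and did not pass (edgeR adjusted p = 0.284, 0.083 and 0.698). In the contractile list 6 of 18 members were called higher, 8 when adjusted over the list alone (camera adjusted p = 9.9e-04; adjusted p = 0.663 with an estimated correlation). Pericytes and vascular smooth muscle also express ACTA2 and TPM2, and their list was called higher as well (camera adjusted p = 0.0241; adjusted p = 0.663 with an estimated correlation). Its median of 0.78 became 0.44 without Control 1, 0.055 with library sizes alone, 0.035 after background subtraction and 0.25 among abundant genes. Of the matrix proteases and inhibitors, CTSK (1.68 ± 0.36) and MMP16 (1.83 ± 0.44) rose, 2 of 19 members over all genes and 2 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.267). MMP2 (1376 ± 1014 CPM against 343 ± 232, adjusted p = 0.0572) and MMP14 (0.96 ± 0.49, adjusted p = 0.176) did not pass. The calls of the matrix and contractile lists were lost when the olfactory receptor background was subtracted. Their medians moved from 0.90 to 0.80 for collagen processing, from 0.83 to 0.36 for collagens, from 0.99 to 0.39 for glycoproteins and from 0.85 to 0.26 for contractile genes. The calls were also lost among abundant protein-coding genes scaled to themselves, with medians of 0.56, 0.36, 0.36 and 0.32 in that order. Single libraries moved 2 of the medians of the main processing by over 1.5 times: collagen processing was at 0.55 without Dupuytren's 3, and glycoproteins were at 0.65 without Dupuytren's 1, 0.44 without Dupuytren's 3 and 1.60 without Control 1. Both alternatives were chosen after seeing the data.

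**Figure D2:**
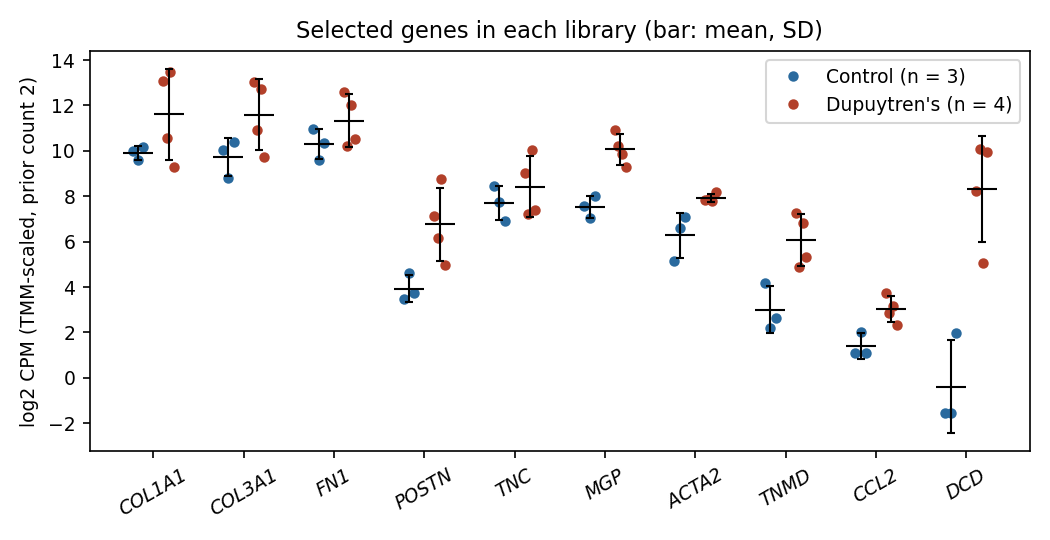
Level of selected genes in each library (log2 CPM, TMM-scaled, prior count 2), with the mean (horizontal line) and SD of each group. COL1A1 spans 9.30 to 13.48 in the 4 Dupuytren's libraries and 9.58 to 10.17 in the 3 control libraries, whereas the groups do not overlap for POSTN, MGP, ACTA2, TNMD, CCL2 or DCD.

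Among growth factor genes, TGFB2 and TGFB3, ligands of the TGF-beta receptors, rose by 1.48 ± 0.38 and 1.42 ± 0.44 (TGFB3 by 0.79 without Dupuytren's 1), and TGFB1 did not pass (0.49 ± 0.31, edgeR adjusted p = 0.262). TGFB1 was at -0.18 with library sizes alone and -0.06 after background subtraction. TGFB2 and TGFB3 were at 1.18 and 0.89 after that subtraction and did not pass (edgeR adjusted p = 0.156 and 0.275). The TGF-beta and BMP list held 2 called members of 23, 1 when adjusted over the list alone, and was called higher (camera adjusted p = 0.0364; adjusted p = 0.667 with an estimated correlation). Its median of 0.33 became -0.35 with library sizes alone, -0.32 after background subtraction and -0.06 among abundant genes scaled to themselves, and it was 0.16 without Dupuytren's 3, 0.14 without Control 2 and 0.62 without Control 1. In the Wnt list, SFRP1 and SFRP2, secreted Wnt antagonists, and CTNNB1, or beta-catenin, rose by 1.72 ± 0.39, 1.46 ± 0.37 and 0.87 ± 0.25. These were 3 of 24 members, 3 when adjusted over the list alone. After background subtraction SFRP1, SFRP2 and CTNNB1 were at 1.18, 0.75 and 0.24. They did not pass there (edgeR adjusted p = 0.127, 0.267 and 0.527). SFRP4 had a difference of 1.54 ± 0.62 (adjusted p = 0.104). The Wnt list was not called (camera adjusted p = 0.720), and its median of 0.03 and mean of -0.23 differed in sign.

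The title of the series names proinflammatory cytokines, and several of their transcripts were near the detection limit in the tissue. TNF had 13 reads over the 4 Dupuytren's libraries and 11 over the 3 controls, and IL1B 3 and 6, too few to test. These raw reads are not scaled to depth, and mean total counts were 10512600 in Dupuytren's and 2052850 in control libraries. Relative to depth both genes thus had more reads in the controls. Whether those few control reads are background was not tested, so a difference in either direction is not settled. IL6 stood at 1.49 ± 0.351 CPM against 2.49 ± 1.16 (log2 difference -0.73 ± 0.85, edgeR adjusted p = 0.547). It had 9, 11, 9 and 21 reads in Dupuytren's 1 to 4 and 5, 9 and 5 in Control 1 to 3. Those control reads were near the olfactory receptor background, at 2.51, 4.48 and 2.55 reads per kb for 2069 bases of exon. IL6 was not testable after background subtraction, so the direction of its difference is not settled. IL33, an alarmin, and IL6ST, the shared receptor subunit of the IL6 family, rose by 1.36 ± 0.31 and 1.21 ± 0.33. After background subtraction IL33 and IL6ST were at 0.85 and 0.49 and did not pass (edgeR adjusted p = 0.124 and 0.325). IL18, another alarmin cytokine, fell, with 5.13 ± 0.304 CPM against 14.6 ± 6.40. It had 28, 52 and 32 reads in Control 1 to 3, and after background subtraction it was at -2.11 and did not pass (edgeR adjusted p = 0.0814). Of 15 tested members of the cytokine list, 2 were called higher and 1 lower, 5 and 1 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.222).

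CCL2, a monocyte chemoattractant, was at 8.34 ± 3.54 CPM against 2.44 ± 1.15 (log2 difference 1.77 ± 0.58, edgeR adjusted p = 0.0531). CXCL14 was the 1 chemokine called of 9 tested (1.84 ± 0.52), with 2 when adjusted over the list alone (camera adjusted p = 0.267 for the list). It stood at 245, 678, 111 and 450.1 CPM in Dupuytren's 1 to 4. The sweat gland list and TMM-scaled DCD (302, 1081, 33.3 and 998 CPM) gave the same order of these libraries. In Control 1 to 3 CXCL14 stood at 85.4, 94.1 and 129.9 CPM, so the groups overlapped. Among NF-kappaB targets VCAM1, an adhesion molecule, rose by 1.16 ± 0.36, 1 of 20 and 0 when adjusted over the list alone (camera adjusted p = 0.116). The list of interferon-stimulated genes was called higher with a median of 0.69 over 19 tested members, of which 0 passed when adjusted over the list alone (camera adjusted p = 0.0037; adjusted p = 0.663 with an estimated correlation). HLA-DRA, HLA-DPB1, B2M and CD74 of the antigen presentation list rose by 1.07 to 1.76, 4 of 18 and 5 when adjusted over the list alone (camera adjusted p = 0.0034; adjusted p = 0.663 with an estimated correlation). Without Dupuytren's 4 the medians of the interferon and antigen presentation lists were 0.42 and 0.38 (0.69 and 0.64 with it). With library sizes alone the medians of the interferon and antigen presentation lists were -0.09 and -0.12, and that of antigen presentation was -0.15 among abundant protein-coding genes scaled to themselves. Immediate-early and stress genes (0 of 23 called, 0 when adjusted over the list alone, camera adjusted p = 0.228) and proliferation genes (0 of 18 and 0, camera adjusted p = 0.716) were not called.

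Transcripts of the ribosome and of mitochondrial energy metabolism gave the list calls with the smallest p. All 29 cytosolic ribosomal protein genes of the list had a positive log2 fold change, with a median of 1.26. Of these, 17 were called higher, and 29 when adjusted over the list alone (camera adjusted p = 7.0e-10; adjusted p = 0.663 with an estimated correlation). RPL4 was at 889 ± 312 CPM against 305 ± 96.1. Of 13 mitochondrially encoded mRNAs, 3 were called, MT-ND4L, MT-CO3 and MT-CYB, and 11 when adjusted over the list alone (median 1.43, camera adjusted p = 6.5e-04; adjusted p = 0.663 with an estimated correlation). The share of counts on mitochondrial mRNAs was 3.21% ± 1.73 (SD, n = 4) against 1.97% ± 0.301 (n = 3; exact p = 0.314), with Dupuytren's 3 below every control. Of 23 nuclear genes of the respiratory chain, 6 were called and 13 when adjusted over the list alone, with NDUFA1 (1.80 ± 0.43), NDUFB1 (1.53 ± 0.37) and COX5B (1.34 ± 0.33) in front (camera adjusted p = 6.0e-06; adjusted p = 0.663 with an estimated correlation). Of the hypoxia and glycolysis list, TPI1 (1.44 ± 0.34) and PGK1 (1.02 ± 0.26), both glycolytic enzymes, rose with GAPDH, LDHA and P4HA1. These were 5 of 19 and 8 when adjusted over the list alone (camera adjusted p = 0.0077, and adjusted p = 0.663 with an estimated correlation). Background subtraction moved the median of this list from 0.70 to 0.26 and that of the respiratory chain list from 0.85 to 0.37. Of 10 long noncoding RNAs of a list written as nuclear-retained, 4 were called higher, OIP5-AS1, SNHG1, GAS5 and NORAD, and 4 when adjusted over the list alone (camera adjusted p = 0.0242; adjusted p = 0.663 with an estimated correlation). NORAD and OIP5-AS1 are known mainly from the cytoplasm, and SNHG1 and GAS5 as spliced hosts of small nucleolar RNAs, so the list does not stand for nuclear RNA. Its median of 0.79 became 0.06 with library sizes alone and 0.46 without Dupuytren's 1. Among abundant protein-coding genes scaled to themselves, the ribosomal protein and mitochondrial mRNA lists were called with the preset correlation (camera adjusted p = 4.8e-09 and 0.0075). The estimated correlation was not run for that setting. There edgeR called 0 single genes (988 at an unadjusted p under 0.05).

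**Figure D3:**
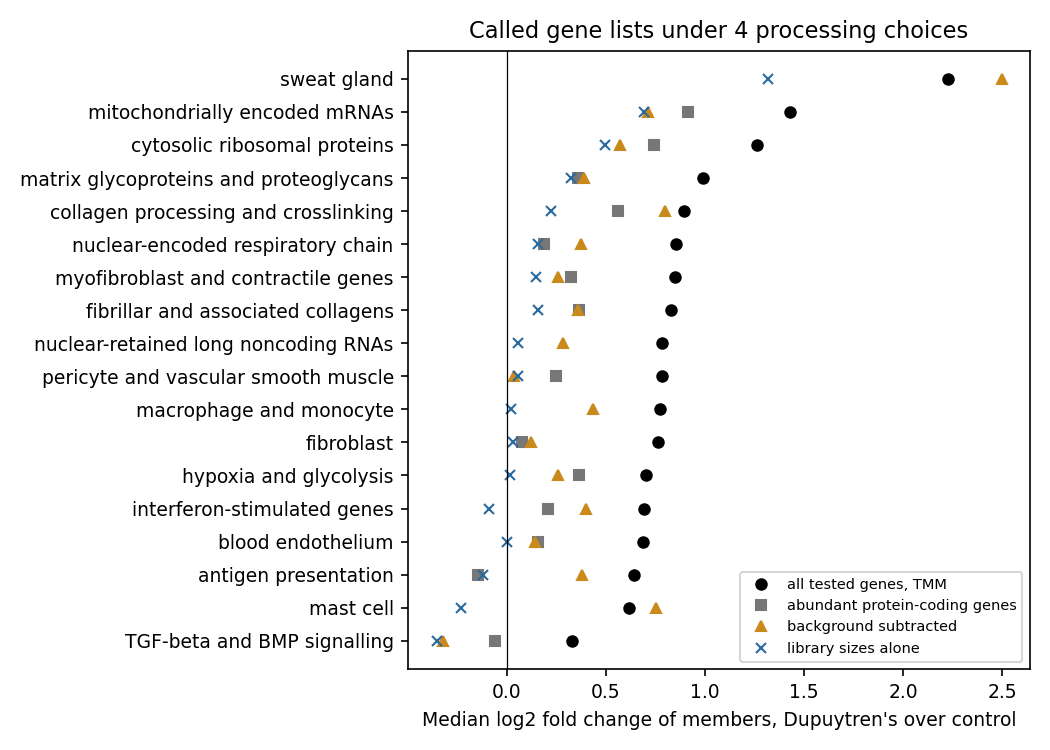
Median log2 fold change (Dupuytren's over control) of the tested members of each of the 18 lists called by camera, under the main processing and 3 alternatives; lists with fewer than 5 tested members under an alternative have no mark for it. The TGF-beta and BMP list lies at 0.33 in the main processing and at -0.35 with library sizes alone, while the ribosomal protein list lies between 0.49 and 1.26 in all 4.

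Markers of several cell types differed with the groups. DCD, the sweat gland gene of the antimicrobial peptide dermcidin, had 239, 697, 31.0 and 858 library CPM in Dupuytren's 1 to 4 and 0, 0 and 4.32 in Control 1 to 3 (log2 difference 8.72 ± 1.77, edgeR adjusted p = 0.0298). It did not pass without Control 3, where the remaining controls held 0 reads and a fitted value is no bound. SCGB1D2, another secretory gland gene, had 11, 104, 10 and 90 reads in Dupuytren's 1 to 4 and 1, 0 and 0 in Control 1 to 3. In the sweat gland list 2 of 9 members were called higher, 2 when adjusted over the list alone (camera adjusted p = 0.0034; adjusted p = 0.663 with an estimated correlation). Of the keratinocyte list KRT5, of basal epidermis, rose by 3.52 ± 0.97, 1 of 15 and 0 when adjusted over the list alone (camera adjusted p = 0.138). Adipocyte genes (0 of 14 called, 0 when adjusted over the list alone, camera adjusted p = 0.138) were uneven within both groups, with the fat cell hormone ADIPOQ at 17.2, 271, 3.89 and 134 library CPM in Dupuytren's 1 to 4 and 19.2, 19.4 and 120 in Control 1 to 3.

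RGS5, ABCC9 and ITGA8, expressed by pericytes and vascular smooth muscle, rose by 1.93 ± 0.37, 1.25 ± 0.28 and 2.13 ± 0.51. CSPG4 and DES of the same list fell by 1.14 and 3.11 on the log2 scale. The list had 3 of 11 members called higher and 2 lower, 5 and 2 when adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.663 with an estimated correlation). PECAM1 (1.09 ± 0.34) and EMCN (1.42 ± 0.41) of blood endothelium rose, 2 of 12 and 5 when adjusted over the list alone (camera adjusted p = 0.0046; adjusted p = 0.663 with an estimated correlation). DPT and FAP of the fibroblast list rose by 1.16 ± 0.30 and 1.64 ± 0.50 (FAP by 1.03 without Dupuytren's 1), 2 of 12 and 2 when adjusted over the list alone (camera adjusted p = 0.0073; adjusted p = 0.663 with an estimated correlation). TYROBP rose by 1.45 ± 0.45 among macrophage genes, 1 of 16 and 0 when adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.670 with an estimated correlation). Background subtraction moved the median from 0.68 to 0.14 for blood endothelium, from 0.76 to 0.12 for fibroblasts and from 0.77 to 0.44 for macrophages. Mast cell genes were called as a list with 0 of 9 members called and 0 when adjusted over the list alone (camera adjusted p = 0.0389; adjusted p = 0.667 with an estimated correlation). Their median of 0.62 became -0.23 with library sizes alone, 0.36 without Dupuytren's 1 and 1.02 without Control 2.

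TNMD, or tenomodulin, a membrane protein of tendon cells, rose by 3.18 ± 0.74 (edgeR adjusted p = 0.0310), 1 of 14 in the tendon and cartilage list and 1 when adjusted over the list alone (camera adjusted p = 0.241). PRG4, or lubricin, was at 262 ± 132 CPM against 767 ± 390.2 and did not pass (adjusted p = 0.0553). In the bone list SPP1 rose by 3.55 ± 1.03 and DMP1 fell by 2.42 on the log2 scale, 1 higher and 1 lower of 7 and the same counts when adjusted over the list alone (camera adjusted p = 0.716). TNNI1 of slow skeletal muscle fell by 2.78 on the log2 scale (1 of 8, 1 when adjusted over the list alone, camera adjusted p = 0.202). CD247 of T cells fell by 2.34 (1 of 8, 1 when adjusted over the list alone, camera adjusted p = 0.391). Both genes were higher in the controls, as the olfactory receptor reads were. After subtraction of that background CD247 was at -2.75 (edgeR adjusted p = 0.191). TNNI1 had too few reads left to test, so its control reads cannot be told apart from the background. The lists of B and plasma cells (0 of 5 called, camera adjusted p = 0.227), lymphatic endothelium (0 of 7, camera adjusted p = 0.925), Schwann cells (0 of 11, camera adjusted p = 0.391) and neutrophils (0 of 3, too few for camera) had no called member, and 0 when adjusted over the list alone.

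Of the 34 lists tested by camera, 18 were called, all higher. With an estimated correlation 0 were called (lowest adjusted p = 0.663 with an estimated correlation), by fry 0 (lowest adjusted p = 0.0634), and by rank-based camera 18. After background subtraction camera called 0 lists (lowest adjusted p = 0.0808). The ribosomal protein median fell from 1.26 to 0.57, while the sweat gland median was 2.50 (2.23 before, and 1.17 without Dupuytren's 2) and the mast cell median 0.75 (0.62 before, 0.36 without Dupuytren's 1 and 1.02 without Control 2). The libraries of the 2 groups separated on the first principal component, which held 65.3% of the variance. Spearman correlations across genes were 0.902 to 0.949 between Dupuytren's libraries, 0.867 to 0.910 between control libraries and 0.751 to 0.903 between groups.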

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

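The tests of nuclear RNA, of raw counts and DCD reads against depth, of the spread of ribosomal proteins between libraries and of control reads per kb were chosen only after the results they bear on were seen, and background subtraction, thinning and the abundant gene set were chosen after seeing the data.

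Single Dupuytren's libraries stood apart from the other 3 in 7 of 165 sets of 4 values by Dixon's criterion, where chance gives about 1 in 20. Dupuytren's 3 had olfactory receptor reads of 219 CPM (the others 23.5 to 50.6) and 23660 genes detected after thinning (the others 19848 to 20484). Dupuytren's 3 also had C4orf3 at log2 CPM 6.27. Dupuytren's 2 had 12.4% of counts on 7SL and 7SK RNA (the others 4.58 to 5.56%) and PALLD at 8.05. Dupuytren's 4 had ACTA2 at 8.17 and PCA3 at -0.12.

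The first pattern is that genes lower in Dupuytren's tissue were mostly low-abundance noncoding genes, pseudogenes and genes foreign to the tissue, with 61 of 118 tested olfactory receptors called lower. Lower depth alone is argued against, since 1885 of the 1999 lower calls had a higher mean raw count in the shallower control libraries. Those genes were selected as lower in the same data, which favours such counts. Olfactory receptor genes were not selected by the calls. Their raw reads were at least 1867 in each control library and at most 1404 in each Dupuytren's library. Thinning left 731 of the lower calls testable, with a median log2 fold change at 110.5% of that of the same genes at full depth. Thinning keeps the expected share of each gene in its library, so that value decides nothing about depth. Unspliced nuclear RNA cannot be told apart from other sources, because a list written as nuclear-retained RNAs had a median of 0.79 in the other direction but 0.06 with library sizes alone, 0.46 without Dupuytren's 1 and 0.29 after background subtraction. A candidate explanation is genomic DNA in the control libraries. Olfactory receptor counts there rose with exonic length (Spearman 0.629 across genes, permutation p = 1e-04, the smallest possible). Reads spread over exons from another source, such as unspliced RNA, would rise with length too, so this does not single out DNA. After subtracting the olfactory receptor background, 2.30% of the lower calls (46 of 1999) were still called. That loss was not specific, as only 5 of 1440 higher calls were kept (median log2 fold change 1.08 before and 0.71 after). The count filter removed 1055 lower calls, and of the 944 still tested (median -3.69, and -3.04 for the same genes before) 60.3% had control reads per kb within the central 95% of olfactory receptor genes (78.9% of the 1997 lower calls with a known length), a share that selecting genes with reads above the background lowers, so it decides nothing and uneven background and lower expression cannot be told apart for them.

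The second pattern is the higher level of ribosomal protein and respiratory chain mRNAs. Among abundant protein-coding genes scaled to themselves the ribosomal protein median lay 0.74 above that of all those genes, past the margin of 0.3 set beforehand, and the difference was 1.79 to 2.68 within Dupuytren's and 1.33 to 1.68 within control libraries; that margin ignored the spread between libraries, by which the difference of 0.60 did not pass (exact permutation p = 0.0857), so scaling to background-laden genes with chance and a change in these mRNAs cannot be told apart. With scaling over all genes the ribosomal protein median was 1.26, and the respiratory chain list, at a median of 0.19 among abundant genes, was not called there (camera adjusted p = 0.265). For transcript length, the median of 0.74 lay 0.59 above that of 1000 sets matched on exonic length (0.15) and 0.22 above the highest of them, less than the margin of 0.3 set beforehand, and library by library the difference was 0.46 (exact p = 0.143), so length bias cannot be told apart from a change either. Disease state and tissue composition remain open and were not tested.

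The third pattern is sweat gland and keratin transcripts, carried mostly by Dupuytren's 2 and 4: the sweat gland median of 2.23 became 1.17 without Dupuytren's 2, and the keratinocyte median of 2.14 became 1.07 without Dupuytren's 4. Depth is argued against for DCD, because at the level of the lowest Dupuytren's library the controls would hold 190.5 DCD reads and held 12. The other genes of the pattern were not tested in this way. SCGB2A2 and AQP5 were at 3.11 and 1.71 library CPM in Dupuytren's 3. These levels lay within the control ranges of 2.19 to 11.0 and 1.44 to 5.81, so such a test could not argue against depth for them. Skin with its glands in the Dupuytren's specimens may be the source: after background subtraction the other 7 sweat gland genes tested had a median log2 fold change of 1.99, which was the same with PIP, at 0 reads in the 3 controls, set to its bound against 3 counts per library. Without subtraction the keratinocyte list had a mean log2 CPM of 1.62 and 1.53 in Dupuytren's 1 and 3, below the 2.23 to 2.46 of the controls. The control values may hold background, and after its subtraction the list median was 4.24 (camera adjusted p = 0.0808). KRT5 and KRT14 of that list were at 11.4 and 16.6 CPM in Dupuytren's 1 and at 6.36 and 5.69 in Dupuytren's 3. The controls held at most 5.34 and 2.08 CPM of them. KRT1 and KRT9, of the epidermis and of palmar skin, were at 372 and 155 library CPM in Dupuytren's 4. In each other library they were at most at 6.84 and 3.24. Of the 7 sweat gland genes 4 are keratins shared by other epithelia, and how specimens were dissected is not given in the sources used here.

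Chance was not excluded for the number of genes called. Of the 35 splits of the 7 libraries into 4 and 3, 2 gave as many calls, the real one with 3439 and another with 3619, which set Dupuytren's 3 with the 3 controls against Dupuytren's 1, 2 and 4. In the other 33 splits edgeR called 0 genes, with 106 to 3449 at an unadjusted p under 0.05. The split with 3619 calls differs from the real one by 1 library, so it shares most of the contrast of disease, and those 4 libraries also had the highest olfactory receptor reads; no test separated the 2 readings. For gene lists, 2 of the 35 splits gave at least the real 18, the highest other giving 19, and each of the 34 other splits gave at least 5 (median 12), so a list call by camera with its preset correlation also arose in splits other than the real one.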

How the results depend on the processing

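Background subtraction, abundant genes and thinning were chosen after seeing the data. The number of genes called (3439; 1440 higher, 1999 lower) depended on nearly every choice, and the cause was not tested except where stated. It was 5182 with library sizes alone (107 higher, 5075 lower), 5750 without a filter (2207 and 3543) and 6790 with DESeq2 (5239 lower). It was 9469 with limma-voom (3345 and 6124) and 6759 with 1 surrogate variable (2740 and 4019). With protein-coding genes only it was 976 (297 and 679). Fewer genes were tested there, but 1312 of the higher and 836 of the lower main calls were protein-coding. The smaller number of genes alone therefore does not account for that fall. Higher calls were 844 with median-ratio factors, 350 with upper-quartile factors and 888 without mitochondrial and rRNA genes. Leaving out 1 library gave 0 to 6007 genes, 0 to 2240 higher and 0 to 4279 lower, with fewer samples in each fit; the 0 was without Control 2 (4220 genes at an unadjusted p under 0.05 in edgeR) and 46 without Control 1, 2240 higher without Control 3.

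Background subtraction left 62 genes (11 higher, 51 lower; 51 of them called before), with 3603 at an unadjusted p under 0.05, and 0 lists. Abundant genes gave 0 genes (0 higher, 0 lower) and 2 lists. Thinning gave 1278 genes (330 and 948) and 5 lists, where fewer reads entered. Lists called were 18 with the main processing, 12 to 23 under the planned processing choices, 13 to 19 without 1 library, 0 with an estimated correlation and 0 by fry.

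Of 114 named genes, 4 changed sign with library sizes alone: GBP2 (-0.0235), KIT (-0.042), SMAD4 (-0.10) and TGFB1 (-0.18), where the scaling moved the median of all genes to -0.75. TGFB1 was at -0.058 after background subtraction and -0.0069 among abundant genes. The remaining settings changed the sign of 0 of the named genes that they tested. Background subtraction tested 104 named genes and the abundant set 67, and IL6 was in neither. Without Control 2, 77 of 113 named genes lost their call, and without Control 1, 68 of 114. After background subtraction 68 of 104 named genes lost their call, and among abundant protein-coding genes 47 of 67. The first principal component held 75.6% of variance with the 500 most variable genes against 65.3%. No paired analysis was possible because the labels pair no samples.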

Other observations

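Of the 62 genes called after the background was subtracted, an alternative chosen after seeing the data, 26 were protein-coding, and a few of them are given here. CSRP2 was higher by 3.24 ± 0.41 on the log2 scale (SE), against 2.21 without the subtraction. ATP1B1, a subunit of the sodium pump, was higher by 4.96 ± 0.85 (3.15 without the subtraction). CSRP2 had 21, 32 and 27 reads in Control 1 to 3, and the subtraction took out part of them. Its larger value thus rests on few control reads, and the SE leaves out error in the background. NTN1, or netrin 1, fell by 1.70 on the log2 scale (SE 0.29). The transcription factors KLF2 and KLF4 each fell by 1.48, the clock gene PER1 by 1.59 and the pericyte proteoglycan CSPG4 by 1.72. Without the subtraction their log2 fold changes were smaller, at -1.09 (NTN1), -0.79 (KLF2), -0.84 (KLF4), -0.94 (PER1) and -1.14 (CSPG4). The edgeR adjusted p of all these genes was 0.0472 to 0.0489 after the subtraction. KLF2, KLF4 and PER1 had not been called without the subtraction (adjusted p = 0.0676, 0.0725 and 0.0515). Very large fitted values in that setting, as for HDAC8, came from groups that the subtraction had put near 0 and are no bounds. These genes were named after their values were seen.

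The share of counts on structural RNAs varied between libraries, and its differences between groups did not pass. Small nuclear RNAs made up 1.57, 6.56, 0.738 and 1.78% of counts in Dupuytren's 1 to 4 and 0.785, 0.391 and 0.497% in Control 1 to 3 (exact permutation p = 0.171), and annotated ribosomal RNA genes 6.87% ± 1.83 (SD, n = 4) against 2.74% ± 0.851 (n = 3; exact permutation p = 0.0571, adjusted 0.0935). MALAT1, a nuclear noncoding RNA, took 2.89% ± 0.618 and 2.85% ± 0.399 (exact permutation p = 0.943), a difference smaller than the spread between libraries.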
